A study of Homo sapiens with 12 samples.

How the data were processed

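U2OS cells, an established human osteosarcoma line, were measured on Illumina Human-6 v2 expression BeadChips, which read the 3′ amplified, biotin-labelled copies of total RNA with bead-bound oligonucleotide probes. Per the labels, the cells carried a lentiviral short hairpin RNA against the PRC transcript or a control hairpin, and stable clones were selected with blasticidin. Whether a group is 1 clone or a pool of clones is not given in the sources used here, so a difference between clones cannot be told apart from an effect of the hairpin in any comparison. PRC is the PGC-1-related coactivator, whose gene symbol is PPRC1. The 12 arrays form 4 groups of 3: shRNA4 and its control, and shRNA1 and its control, whose titles alone carry a year. These 2 sets of 6 arrays are called the shRNA4 set and the shRNA1 set. Per the labels' protocols, amplified RNA was hybridised in triplicate, and nothing says that the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

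The values used are the log2-scale values the authors deposited for each probe and array. Lumi 1.7.18 is named in the submitters' processing notes; the transform, background step and summary are not given in the sources used here. The log2 scale is inferred from the values, which range from 7.61 to 15.7 in the shRNA4 set and from 4.94 to 15.7 in the shRNA1 set. The sets were normalised apart. In the shRNA4 set the sorted values of the 6 arrays differed by at most 0.000401, every median was 7.92, and 777 of 48687 probes were empty. In the shRNA1 set the sorted values differed by up to 0.173 and the medians lay between 5.15 and 5.16. The floor of both scales is compressed, more so in the shRNA4 set. Log2 fold changes of dim genes may therefore be understated, and those of shRNA4 more than those of shRNA1, which was not measured. The 2 sets thus lie on different scales. The planned contrast between the 2 control groups was not run for this reason.

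Probe names came from the platform annotation, which lists 23710 of the probes, 23675 with a single symbol and 35 with several; 24977 probes are unnamed here. Symbols were updated through Entrez numbers in a gene table of assembly GRCh38.p14 for 23639 probes. That table also gave the order of genes along chromosomes; the array's own build is not given in the sources used here, so no coordinates are printed. Probes with values on all arrays numbered 47910. Those with a mean over the 12 arrays above the median of all probes were kept (23955), and the brightest probe stood for each gene, which left 13763 genes. The number of arrays limits the precision, and no detection p-values were used here.

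A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 2.18 prior degrees of freedom). It gave shRNA1 minus its control, shRNA4 minus its control, and the first minus the second. All tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen, fallen or changed. The third contrast crosses the 2 scales; quantile normalisation over all 12 arrays was run beside it. PPRC1 was also tested by exact permutation. For 40 gene lists written before the data were examined, limma's camera compared the members with all other genes at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. A list needed at least 3 tested members, which 39 had; the mitochondrially encoded genes did not. Camera with an estimated correlation and limma's fry were alternatives.

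The genes named are PPRC1; for each hairpin the 10 largest rises and the 10 largest falls among genes that passed the test, changed at least 1.5-fold and showed no overlap between the 3 arrays of each group; up to 4 members of each described list with the largest changes among those that passed; 8 rising and 8 falling genes past the same thresholds in both comparisons; 6 in each direction for the difference; and 5 genes called in opposite directions. This rule, the lists, the tests of genes and lists and all alternatives but 2 were fixed before the data were examined. Besides genes marked so in the text, MTHFD2, ASNS, CBS, PSAT1, BUB3, RPA1, IDH3B, NDUFA9, COL6A3, COL11A1 and H2AJ are named outside this rule. For these, other probes and values after subtraction of neighbouring genes are not given. The alternatives covered normalisation, filters, variance models, array weights, size thresholds, probe summaries, a plain pooled-variance test, the replicate number as a block and leaving out each array. Added after seeing the data were leaving out both arrays numbered 1 of the shRNA1 set, and subtracting from every gene the running median of its 10 neighbours on each side.

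The replicate numbers come from the titles. Correlations of deviations from the group means between same-numbered arrays were 0.73, 0.45 and 0.58 in the shRNA1 set. With another number the highest were -0.52, 0.37 and 0.40. The numbers therefore pair the arrays there, most clearly array 1, and the main fit does not use this pairing. In the shRNA4 set the correlations were 0.11, -0.50 and -0.38, so the numbers do not pair the arrays. The replicate block was applied to both sets.

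The gene test was run on simulated data with the real genes' control levels and a single SD per gene, averaged over the groups. In it 200 of the 13763 genes were changed per hairpin. For shRNA1 it recovered 76.1% of 67 genes changed 1.5-fold, 94.0% of 67 changed 2-fold and 100% of 66 changed 4-fold; for shRNA4 these shares were 74.6%, 95.5% and 98.5%. For the difference they were 70.8% of 65, 86.6% of 67 and 100% of 66. Unchanged genes made up 6.74% of its calls for shRNA1 and 8.21% for shRNA4. The simulated spread was the same in both sets and held no pairing of arrays, unlike the data. The shares for shRNA1 and shRNA4 are therefore alike by design and do not show the power in either set. A simulated list of 30 shifted genes was called, and 0 of 38 random lists were. The simulated noise was independent between genes. It therefore does not test camera on lists whose genes vary together, where the estimated correlation reached 0.61 (mitosis). Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.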

Results

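Gene expression was profiled on 12 arrays from U2OS osteosarcoma cells that carried a stable hairpin against the PRC transcript or a control hairpin, to ask which transcripts depend on this member of the PGC-1 coactivator family, known as a partner of nuclear respiratory factors. Each hairpin had its own control, with 3 arrays per group; the labels do not say whether a group is 1 clone or a pool, so the hairpin and the clone cannot be told apart in any comparison. Arrays of a group correlated across genes with r between 0.989 and 0.999, and the median SD of a gene within a group lay between 0.05 and 0.09 on the log2 scale. A two-sided permutation test of 3 against 3 arrays cannot go below p = 0.1.

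The target transcript was lower with shRNA4 and not detectably lower on the arrays labelled shRNA1. PPRC1, read by the single named probe ILMN_1796210, had a mean of 10.68 ± 0.05 (SD, n = 3) in the control and 10.09 ± 0.04 (SD, n = 3) with shRNA4, with no overlap of arrays. The log2 fold change was -0.59 with a 95% interval from -0.999 to -0.18, and the exact permutation p was 0.1. In limma its adjusted p was 0.0901 with all 12 arrays, 0.00127 with the shRNA4 set fitted alone and 0.00627 with the replicate number as a block, within a range of 0.00127 to 0.232 over all alternatives. On the shRNA1 arrays PPRC1 was at 9.67 ± 0.31 (SD, n = 3) against 9.70 ± 0.39 (SD, n = 3) in its control, a log2 fold change of -0.03 with an interval from -0.44 to 0.38 (limma adjusted p = 0.928, exact permutation p = 0.9). The difference between both changes was 0.56 with an interval from -0.02 to 1.14 (limma adjusted p = 0.194). The target therefore does not bear out the shRNA1 label, and directions below are given for "the arrays labelled shRNA1". Which part of the transcript the probe reads is not given in the sources used here.

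**Figure D1:**
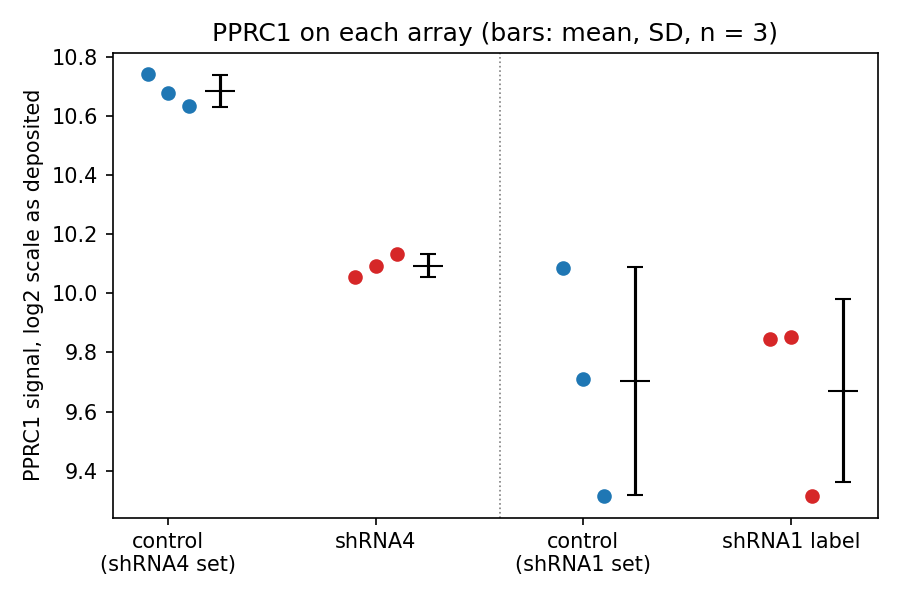
PPRC1 signal on the deposited log2 scale (y axis) for each of the 12 arrays (points) in the 4 groups (x axis), with mean and SD of 3 arrays beside them. The shRNA4 arrays lie below their control, with means of 10.09 and 10.68; the arrays labelled shRNA1 overlap theirs, with means of 9.67 and 9.70, and the dotted line parts the sets, which are on different scales.

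On the arrays labelled shRNA1, transcripts of replication-dependent histone genes and of ANXA10 fell, and those of LUM, PLAC8 and AKR1C3 rose. ANXA10, a calcium-dependent phospholipid-binding annexin, went from 12.68 to 5.42 on the log2 scale, a fitted change of -7.25. H2AC18 (-5.51, SE 0.10), H4C8 (-5.41), H4C3 (-4.71), H2AC6 (-4.71), H2BC21 (-4.24), H1-2 (-3.95) and H2BC11 (-3.84), all core or linker histone genes, made up most of the other large falls, followed by the vesicle fusion protein gene VAMP8 (-3.75) and RAC2 (-3.71). LUM, a proteoglycan of the extracellular matrix, rose by 5.47 (SE 0.17), PLAC8 by 4.15 (SE 0.39), and AKR1C3, a steroid and aldehyde reductase, by 2.94. The cancer-testis genes SPANXA2 (3.19), SPANXC (3.18) and GAGE12J (3.01) rose too; each has near-identical copies on the X chromosome that a probe may not separate. CCDC62 (2.88), the serpin gene SERPINB7 (2.66), the chemokine receptor gene ACKR3 (2.53) and the Notch glycosyltransferase gene LFNG (2.41) complete the largest rises. ANXA10 and RAC2 ended, and SERPINB7 (5.19) and EPCAM began, below the 75th percentile of all probes on their arrays (5.53 with the label shRNA1 and 5.55 in its control), so the sizes of these changes are not measured exactly. In total 4049 of 13763 genes changed in limma, 2119 upward and 1930 downward; 1453 of them changed at least 1.5-fold and 427 at least 2-fold. The 3 arrays of each group did not overlap for 37.6% of genes, against 10% by chance. The plain pooled-variance test called 1701.

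Among the lists, the 14 tested histone genes had a median of -2.90 on the arrays labelled shRNA1: 0 rose and 10 fell, both over all genes and adjusted over the list alone (camera adjusted p = 1.9e-12; adjusted p = 0.0636 with an estimated correlation). Targets of ATF4, the transcription factor of the amino acid stress response, rose: 21 of 33 rose and 4 fell, 22 and 4 adjusted over the list alone (camera adjusted p = 0.000131; adjusted p = 0.0796 with an estimated correlation). They were led by the cystathionine lyase gene CTH (1.56), the mTORC1 inhibitor gene DDIT4 (1.52), the cystine transporter gene SLC7A11 (1.34) and NUPR1 (1.30), whereas SHMT2 (-0.59) and DDIT3 (-0.57), named after their values were seen, were among those that fell; another filtered CTH probe changed by 0.57. Of 60 cytosolic ribosomal protein genes 26 rose and 1 fell, 28 and 1 adjusted over the list alone, with RPL13A (1.13), RPL23A (1.05) and RPL7A (0.98) in front (camera adjusted p = 3.49e-06; adjusted p = 0.0796 with an estimated correlation); RPL7A stood at 0.56 after the running median of neighbouring genes was subtracted. Of 19 targets of the antioxidant regulator NRF2, 10 rose and 2 fell, also adjusted over the list alone; the thioredoxin reductase gene TXNRD1 rose by 1.48, AKR1C3 and SLC7A11 as above, and GSTM4 fell by 1.05, with -0.25 on another filtered probe (camera adjusted p = 0.00376; adjusted p = 0.555 with an estimated correlation). Of 26 lysosome and autophagy genes 10 rose and 1 fell, 11 and 1 adjusted over the list alone, among them the cathepsin genes CTSL (1.76) and CTSB (0.68), GABARAPL1 (1.06) and WIPI1 (0.77), with CTSB at 0.40 after that subtraction (camera adjusted p = 0.00571; adjusted p = 0.244 with an estimated correlation).

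With shRNA4 9 of 14 listed histone transcripts fell, and fewer genes changed than on the arrays labelled shRNA1. PLAC8 rose most (2.52, SE 0.39), followed by the neuronal adhesion gene NTM (1.64), the collagen gene COL16A1 (1.64), the myosin light chain gene MYL2 (1.56) and the zinc finger gene ZFP82 (1.45). TUSC3 (1.41), DENND2A (1.40), the deadenylase gene CNOT7 (1.32), EPCAM (1.32) and the centriolar satellite gene PCM1 (1.31) rose as well. TCEAL2 fell by 2.72 (SE 0.27), followed by the tubulin gene TUBB2B (-2.58), the carbonic anhydrase gene CA2 (-2.04) and DPYSL3 (-1.85). H4C8 (-1.97), H2BC11 (-1.75), H2AC6 (-1.68), H2BC21 (-1.65), the amino acid sensing GTPase gene RRAGD (-1.66) and the matrix protein gene TGFBI (-1.63) were the other largest falls. CA2 ended and EPCAM began below the 75th percentile of all probes on their arrays (8.20), so these sizes are not measured exactly, and after subtraction of neighbouring genes TUSC3 stood at 0.93. Other filtered probes changed by 0.55 for TUSC3 and by 0.32 and 1.25 for CNOT7. In limma 1011 genes changed, 495 upward and 516 downward, 262 of them at least 1.5-fold and 59 at least 2-fold; arrays did not overlap for 30.2% of genes, against 10% by chance. This count was 1940 after quantile normalisation over 12 arrays, against 2976 on the arrays labelled shRNA1, and 1572 with the set fitted alone, against 2973, so the gap between the comparisons depends on scaling and on pooling of the spread. It was 2605 with array weights, 473 with the plain pooled-variance test and 1841 without both arrays numbered 1 of the shRNA1 set, while without shRNA4 array 1 or array 3 it was 498 or 521.

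The histone list fell with shRNA4 as well, with a median of -0.46, 0 of 14 rising and 9 falling, also adjusted over the list alone (camera adjusted p = 1.42e-08; adjusted p = 0.184 with an estimated correlation). H4C3, among the largest falls on the other arrays, was at 0.46 with shRNA4 and not called (limma adjusted p = 0.246), although its arrays did not overlap. Cell division lists were shifted downward with few single calls. Of 41 mitosis genes 0 rose and 2 fell, 0 and 4 adjusted over the list alone; these were the kinase gene AURKB (-0.95) and the checkpoint gene BUB3 (-0.23), and the median was -0.23 (camera adjusted p = 3.24e-05; adjusted p = 0.754 with an estimated correlation). Of 41 DNA replication genes 0 rose and 3 fell, 0 and 7 adjusted over the list alone: the nucleotide synthesis genes DUT (-0.94) and RRM2 (-0.39), and RPA1 (-0.48) (camera adjusted p = 0.0211; adjusted p = 0.558 with an estimated correlation). After subtraction of neighbouring genes RRM2 was no longer called (-0.29, limma adjusted p = 0.114) and AURKB stood at -0.62. Another filtered DUT probe changed by -0.15. Of 33 ATF4 targets 0 rose, 5 fell and 28 were not called, 1 rising and 6 falling adjusted over the list alone; the list was shifted downward, with the serine and asparagine pathway genes MTHFD2 (-0.75), ASNS (-0.73), CBS (-0.65) and PSAT1 (-0.50) (camera adjusted p = 0.00823; adjusted p = 0.266 with an estimated correlation). DDIT4, of the same list, was at 1.39 without overlap of arrays, close to its 1.52 on the other arrays, and not called (limma adjusted p = 0.067). Of 22 genes of the TCA cycle and pyruvate dehydrogenase 1 rose and 4 fell, 1 and 5 adjusted over the list alone; PDHX (-0.56), DLST (-0.56) and SUCLG1 (-0.51) fell and IDH3B rose by 0.47 (camera adjusted p = 0.0325; adjusted p = 0.265 with an estimated correlation). Without shRNA4 array 2, or with the filter at the 70th percentile, 3 lists in place of 5 were shifted.

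Genes of the respiratory chain, which PRC is known to regulate through nuclear respiratory factors, moved in both directions. Over all 13763 genes, 2119 rose and 1930 fell on the arrays labelled shRNA1, and 495 rose and 516 fell with shRNA4. Calls in both directions are therefore not particular to these lists. Of 35 complex I genes 6 rose and 8 fell on the arrays labelled shRNA1, among them NDUFA7 (-0.82) and NDUFA13 (0.65); with shRNA4 2 rose, such as NDUFB2 (0.81), and 2 fell, such as NDUFA9 (-0.44). Of 11 complex II and III genes 3 rose on the arrays labelled shRNA1, SDHD (0.71), UQCRC2 (0.52) and UQCRH (0.34), and SDHA fell by 1.29, although its other filtered probe changed by -0.01. Of 11 complex IV genes COX7B alone rose there (0.41) and 0 fell; with shRNA4 SDHA (-0.39) and SDHD (-0.48) were not called, nor was any other gene of these lists in limma. The copper chaperone genes COX17 (-0.98 and -0.67 with shRNA4) and SCO1 (-0.74 and -0.53) fell on both, while the import gene TIMM22 rose on both (1.23 and 0.63) and TOMM22 fell on both (-0.88 and -0.67). After subtraction of neighbouring genes, TOMM22 (-0.50, limma adjusted p = 0.0828) and COX17 (-0.47, limma adjusted p = 0.115) were no longer called with shRNA4. TIMM22 then stood at 0.30 and SCO1 at -0.26 with shRNA4, and SDHA at -0.55, SCO1 at -0.39, TOMM22 at -0.57 and COX7B at 0.25 on the arrays labelled shRNA1, where UQCRH (0.21, limma adjusted p = 0.157) was no longer called. Of 26 import genes 3 rose and 6 fell on the arrays labelled shRNA1, and 2 rose and 2 fell with shRNA4. Of 27 assembly factors 2 rose and 9 fell on the arrays labelled shRNA1, and 2 rose and 4 fell with shRNA4. Camera adjusted p for these lists ranged upward from 0.231 on the arrays labelled shRNA1 and from 0.471 with shRNA4. By fry the assembly factors were shifted downward on the arrays labelled shRNA1 (fry adjusted p = 0.00269). For the other lists there fry adjusted p started at 0.406, and with shRNA4 it started at 0.183. Adjusted over the list alone, complexes I to IV and the import list gave the same counts, and the assembly factors 2 and 9 for shRNA1 and 4 and 5 for shRNA4.

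**Figure D2:**
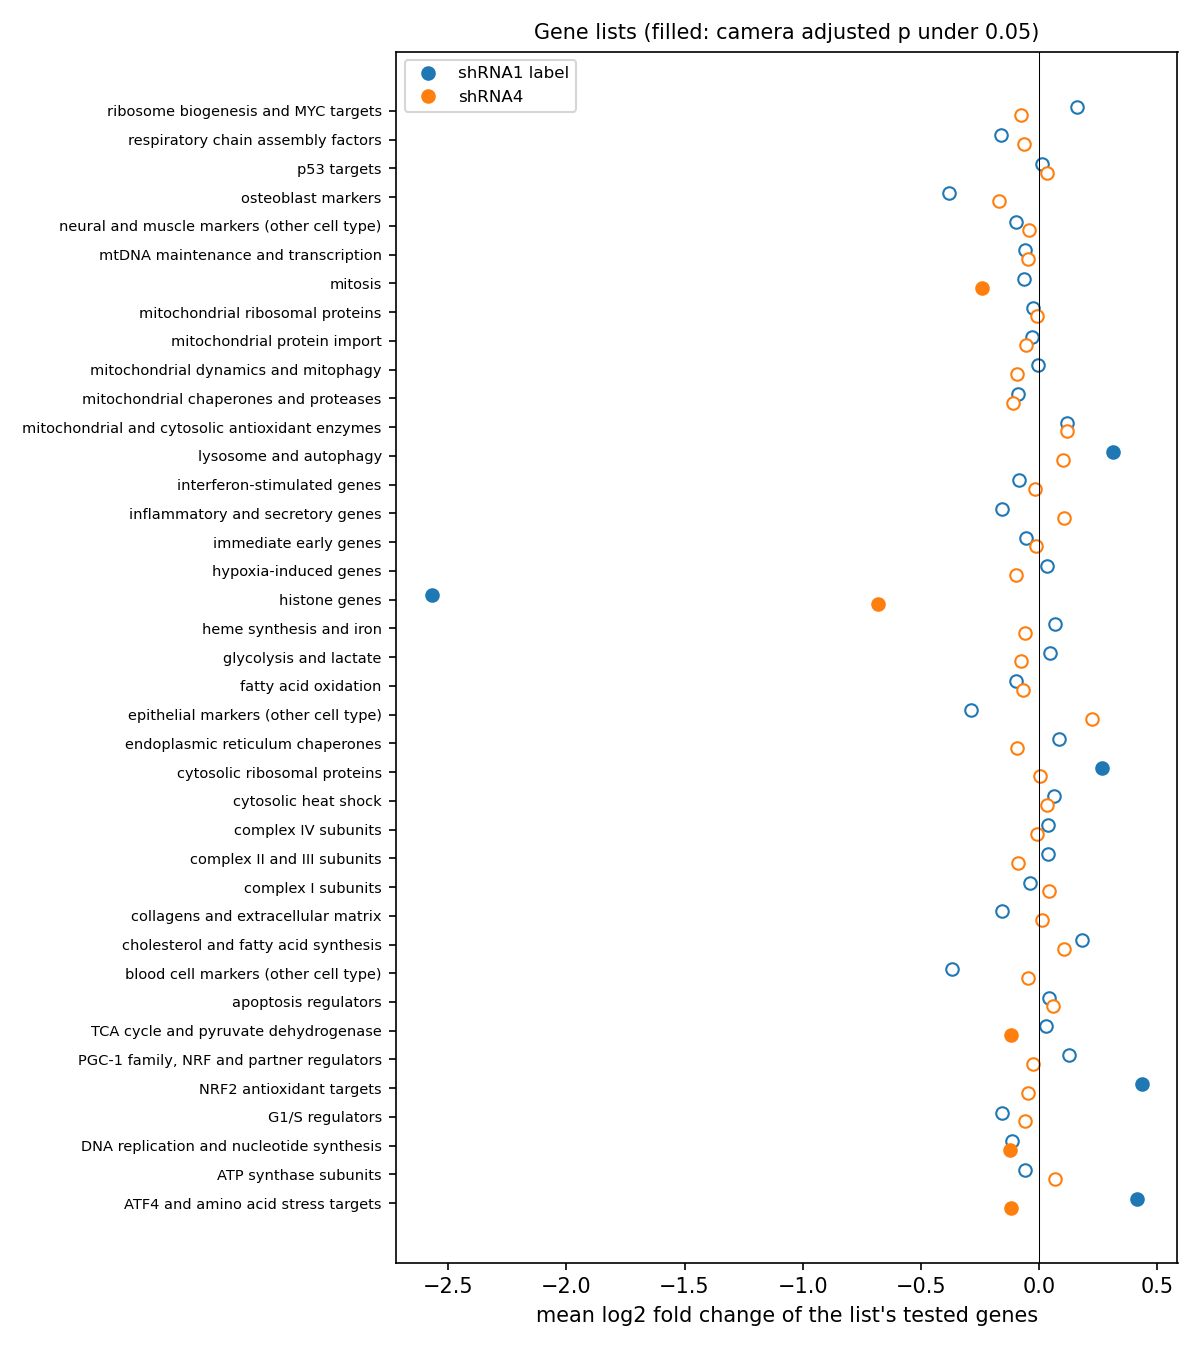
Mean log2 fold change (x axis) of the tested members of each gene list (y axis) for the arrays labelled shRNA1 (blue) and for shRNA4 (orange); filled points have a camera adjusted p under 0.05. The histone list lies at -2.57 and -0.68, and the ATF4 list at 0.42 and -0.12.

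Several histone transcripts and TGFBI fell and PLAC8 rose both on the arrays labelled shRNA1 and with shRNA4. Across the 13763 genes 231 rose in both comparisons, against 76.2 for independent lists, and 285 fell in both, against 72.4. Of the 158 called in opposite directions, 74 rose and 84 fell on the arrays labelled shRNA1, against 79.4 and 69.4 for independent lists. No arrays are shared between both comparisons, but the main fit pools the spread of each gene over both sets. Whether both controls came from the same clone is not given in the sources used here. A trait of common control cells would appear in both comparisons and cannot be told apart from a shared effect of the hairpins. The histone genes H4C8, H2BC11, H2AC6, H2BC21, H2AC18 and H4C14 (-3.70 and -1.38), together with TGFBI and the prostaglandin transporter gene SLCO2A1 (-1.41 and -1.50), were the largest shared falls. A dimmer H4C8 probe past the filter changed by -0.01 on the arrays labelled shRNA1 and by -0.0019 with shRNA4. PLAC8, ZFP82 (2.26 and 1.45) and the thrombin receptor family gene F2RL2 (2.20 and 1.05) rose in both. So did PCM1 (1.42 and 1.31), CNOT7 (1.24 and 1.32), INTS10 (1.15 and 1.15), NEIL2 (1.20 and 1.04) and PSD3 (1.37 and 1.30), which all lie on chromosome 8. Other filtered PSD3 probes changed by 0.02 and 0.07, and by 0.57 and 0.86. SLCO2A1 ended below the 75th percentile of all probes with shRNA4. Of the 20 neighbouring genes on chromosome 8 from XKR6 to INTS10, 14 rose on the arrays labelled shRNA1 and 14 with shRNA4, with medians of 0.75 and 0.72. This window was picked from all 20-gene windows as the one most raised in both comparisons, so its medians are selected extremes. After the running median of neighbouring genes was subtracted, PCM1 stood at 0.98 and 0.86 and CNOT7 at 0.62 and 0.78; with shRNA4 INTS10 stood at 0.74, NEIL2 at 0.68 and PSD3 at 0.86. Across genes, which are not independent replicates, Pearson's r of both log2 fold changes was 0.27 and Spearman's rho 0.19. The number changed in the same direction, 516, was 1108 with array weights, 147 with the plain test and 831 without both arrays numbered 1 of the shRNA1 set, and 289 or 302 without shRNA4 array 1 or 3.

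**Figure D3:**
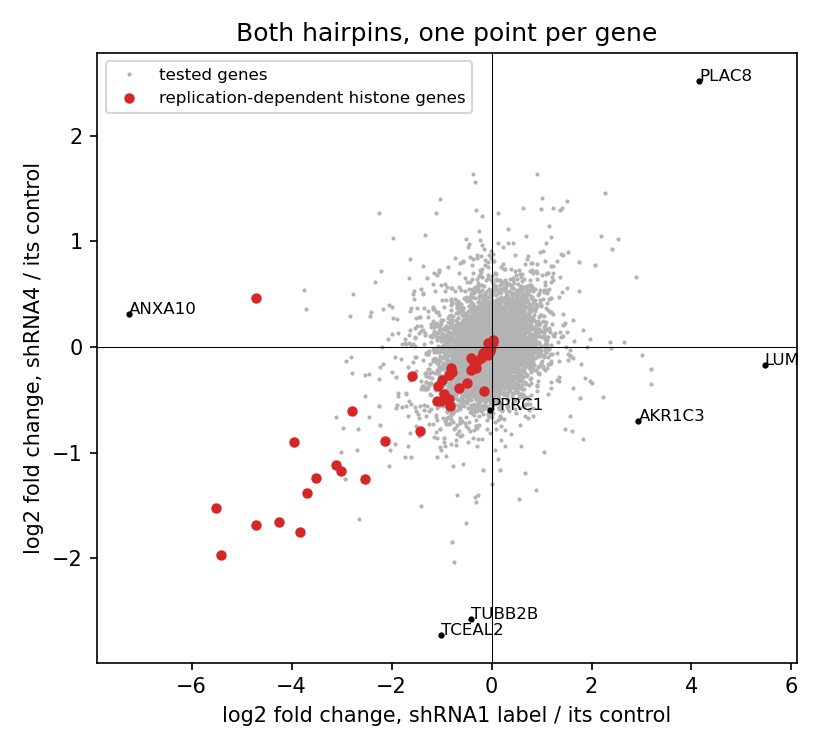
Log2 fold change of each tested gene with shRNA4 (y axis) against that on the arrays labelled shRNA1 (x axis), with replication-dependent histone genes in red. PLAC8 lies at 4.15 and 2.52 and H4C8 at -5.41 and -1.97, while LUM (5.47) and ANXA10 (-7.25) lie near 0 with shRNA4.

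**Figure D4:**
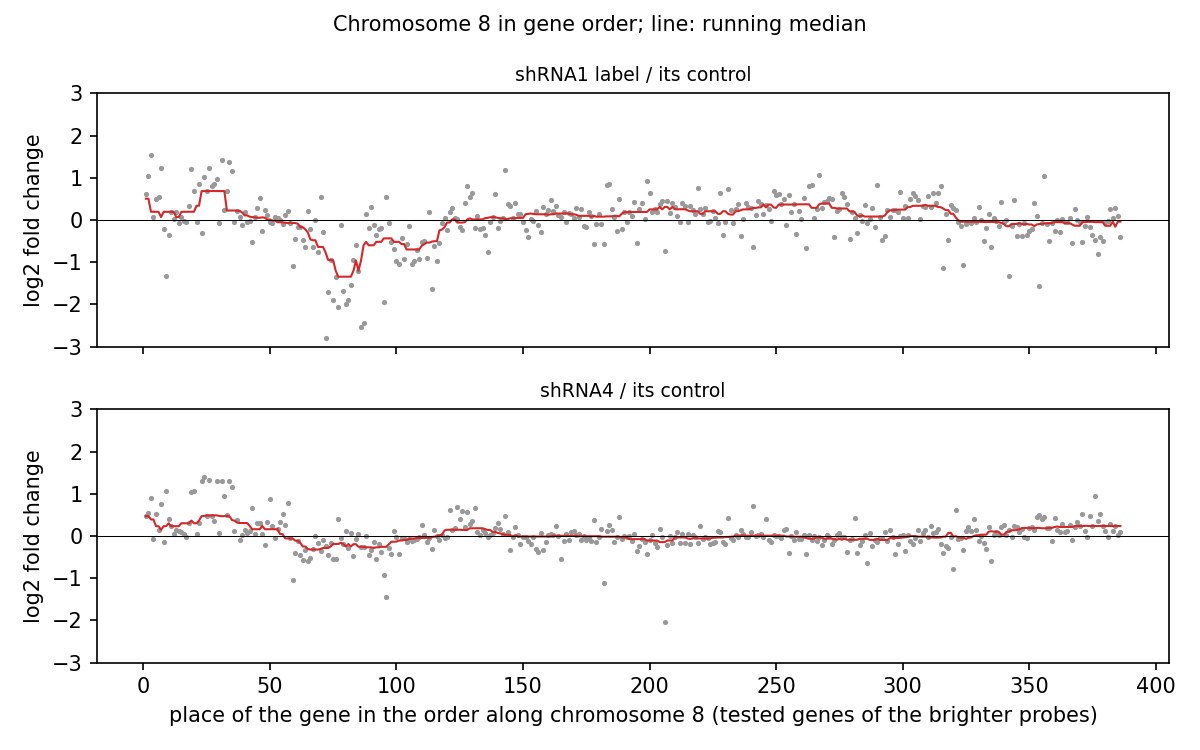
Log2 fold change (y axis) of genes in their order along chromosome 8 (x axis, place in the order) on the arrays labelled shRNA1 (top) and with shRNA4 (bottom), 1 point per gene of the brighter probes and a running median as a line. The window from XKR6 to INTS10 has medians of 0.75 and 0.72, and that from ADRA1A to DCTN6 medians of -1.44 and -0.18. The first was picked as the window most raised in both comparisons, the second as the lowest on the arrays labelled shRNA1.

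The change on the arrays labelled shRNA1 differed from that with shRNA4 for 2239 genes in limma's test of the difference, 1152 higher and 1087 lower on the arrays labelled shRNA1. LUM (difference 5.64, SE 0.24), AKR1C3 (3.64), SPANXC (3.53), SPANXA2 (3.39), GAGE12J (3.08) and the arginine synthesis gene ASS1 (2.70) were higher there. ANXA10 (-7.57, its size not measured exactly), H4C3 (-5.17), VAMP8 (-4.29), RAC2 (-4.07), H2AC18 (-3.99) and the kallikrein gene KLK6 (-3.52) were lower. Called in opposite directions were KLK6 (-2.24 on the arrays labelled shRNA1 and 1.27 with shRNA4), the G protein gene GNG11 (-2.32 and 0.61), ITPKA (-2.17 and 0.36), DENND2A (-1.03 and 1.40) and ASS1 (2.23 and -0.47). After subtraction of neighbouring genes GNG11 (0.55, limma adjusted p = 0.0622) and ITPKA (0.15, limma adjusted p = 0.465) were no longer called with shRNA4, and ASS1 stood at -0.76 there. A dimmer KLK6 probe changed by -0.04 and 0.12. Lists that differed by camera were histone genes (0 higher and 10 lower, also adjusted over the list alone; adjusted p = 1.19e-11, and adjusted p = 0.0388 with an estimated correlation) and ATF4 targets (18 higher and 0 lower, 20 and 1 adjusted over the list alone; adjusted p = 4.19e-07, and adjusted p = 0.0388 with an estimated correlation). Cytosolic ribosomal proteins differed too, with 23 higher and 1 lower, 25 and 1 adjusted over the list alone (camera adjusted p = 2.05e-06; adjusted p = 0.0779 with an estimated correlation), as did NRF2 targets, with 8 higher and 2 lower, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00212; adjusted p = 0.484 with an estimated correlation). Epithelial markers, listed as signs of another cell type, were lower in 4 of 11 and higher in 0, 5 and 0 adjusted over the list alone (camera adjusted p = 0.031; adjusted p = 0.161 with an estimated correlation); the keratin gene KRT8 fell by 2.78 on the arrays labelled shRNA1, and EPCAM rose by 0.63 there and by 1.32 with shRNA4. This test crosses 2 scales. Its count was 1772 after quantile normalisation over 12 arrays, with 1598 of 2238 calls shared in direction, and 3655 with array weights.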

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

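All tests of explanations here were chosen after the results they bear on were seen. By the test of the difference itself, 2239 genes changed differently on the arrays labelled shRNA1 than with shRNA4. Called in opposite directions were 158 genes, 74 and 84 by direction, against 79.4 and 69.4 for independent lists; that number was 24 at 1.5-fold, 28 with the plain test, 436 with array weights, 298 without both arrays numbered 1 of the shRNA1 set, and 74 or 77 without shRNA4 array 1 or 3. Of the lists, the mean difference of log2 fold changes, arrays labelled shRNA1 minus shRNA4, was -1.89 for histone genes, 0.54 for ATF4 targets, 0.48 for NRF2 targets, -0.52 for epithelial markers and 0.26 for cytosolic ribosomal proteins. In data outside the comparisons, 12 of the 777 probes empty in the shRNA4 set changed in the shRNA1 set, 9 of them upward. Among the 7776 filtered probes without a symbol, 853 changed on the arrays labelled shRNA1 and 158 with shRNA4.

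Splits of the arrays bear on the counts of changed genes. In the shRNA1 set 1 of the 10 splits, the real one, gave 4049 genes, and the highest other gave 1, the splits that part all 3 same-numbered pairs included. In the shRNA4 set 1 of the 10, again the real one, gave 1011 genes, and the highest other gave 0. With 10 splits a share under 0.05 cannot be reached. For the difference 2 of 100 drawn splits gave at least 2239 genes; the highest other, with 3354, exchanged the groups within 1 set as wholes, so that both changes were added. For genes changed in the same direction in both comparisons 1 of 100 gave 516, and the highest other, also such an exchange, gave 158. Like the real one, 37 of the 100 part all same-numbered pairs of the shRNA1 set. Of these 37, 2 gave at least 2239 genes for the difference, the real one and the exchange of whole groups. Since that exchange adds both changes, the share could not fall below 0.05, and chance is not excluded there. Of the others, 7 kept the groups of the shRNA1 set whole, mixed those of the shRNA4 set and gave 1358 to 2166. The 28 that mixed the shRNA1 set gave at most 6. For the shared direction 1 of the 37 gave 516. Both the 7 and the 28 gave 0, since a set with mixed groups has hardly any changed genes to share. These splits could hardly have matched the real one, so they do not decide on chance.

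PPRC1 was not lower on the arrays labelled shRNA1. With the number as a block the lower 95% bound was -0.22, above the shRNA4 estimate of -0.59. This argues against differences between array numbers hiding a fall of that size. The bound pools the spread with the shRNA4 set, where the numbers do not pair the arrays. With shRNA4 the block interval itself ran from -0.78 to -0.41. Without the block, the interval of the difference, from -0.02 to 1.14, includes no difference, so a smaller fall is not excluded. An exchange of arrays between both groups finds no partner: 0 of the 6 arrays correlated better with the other group. A probe that reads transcript left in place by the hairpin may account for it and cannot be told apart from an unchanged level, because 1 probe is named. That the arrays hold cells in which the hairpin did not lower the transcript also stays open, untested.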

How the results depend on the processing

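Added after seeing the data were the setting without both arrays numbered 1 of the shRNA1 set and the subtraction of neighbouring genes. PPRC1 was called in no setting for shRNA1. By over 1.5 times 29 counts moved, and the cause was not tested. For shRNA4 8 PPRC1 values crossed the threshold. The main fit pools the spread of all 12 arrays, and PPRC1 varied more in the shRNA1 set. Its SE with shRNA4 was 0.183 in that fit and 0.044 with the shRNA4 set alone. Numbers of genes changed are given in the order shRNA1, shRNA4, difference and both comparisons. At 1.5-fold they were 1453, 262, 1212 and 115, at 2-fold 427, 59, 414 and 26, since fewer genes qualify. The plain test gave 1701, 473 and, for both, 147. Array weights gave 2605, 3655 and 1108 for the last 3. Quantile normalisation over 12 arrays gave 2976, 1940, 1772 and 705, and each set alone 2973, 1572 and, for both, 554; without both arrays numbered 1 the count for shRNA4 was 1841, and 831 for both. Leaving out each array gave 3238 to 4158, 498 to 1242, 1609 to 2540 and 289 to 603; an array left out leaves 2 in its group. PPRC1 with shRNA4 was -0.73 under quantile normalisation over 12 arrays and -0.57 with array weights; it kept -0.59 but passed the threshold with its set alone, the replicate block, the plain test, without both arrays numbered 1, and without array 1 or 3 of the control of the shRNA1 set. Its range without single arrays was -0.62 to -0.56, and for shRNA1 -0.23 to 0.16; its limma adjusted p ranged from 0.00127 to 0.232 for shRNA4 and from 0.375 to 0.968 for shRNA1. Of 5 shifted lists per contrast, an estimated correlation left 0, 0 and 2. Fry called 15 for shRNA1 and 9 for the difference. With shRNA4 fry did not call the mitosis list (fry adjusted p = 0.251) or the DNA replication list (fry adjusted p = 0.083). The 70th percentile filter left 3 for shRNA4, and leaving out arrays gave 5 to 6, 3 to 7 and 5 to 7. The replicate block gave 4643, 1380, 2878 and 698 genes and among PPRC1 and the lists changed only the calls of PPRC1 with shRNA4 and of the ribosome biogenesis list in the difference, which became shifted (adjusted p = 0.03). In the shRNA4 set, where the numbers do not pair the arrays, arrays 2 and 3 correlated better with another number. Subtracting neighbouring genes left 4424 genes for shRNA1, sharing 2412 of the 4049 in direction and turning 84; it shared 553 of 1011 for shRNA4, turning 0, and 1218 of 2239 for the difference, turning 12. Of the named genes' calls it ended 29 of 169 for shRNA1 and 18 of 71 for shRNA4, and it turned EIF4A1 to 0.28 and FIS1 to 0.20. Of the named genes' values, 432 lost and 188 gained their call under some setting; of single lists' values, 27 lost and 38 gained it. The contrast between controls was not run, nor were settings for linear values or other PPRC1 probes, and fitting each set alone gives no difference. Signal near the compressed floor limits changes of dim genes.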

Other observations

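Growth and matrix genes outside the lists shifted by camera changed on the arrays labelled shRNA1. The cell cycle kinase gene CDK6 fell by 1.99, the cyclin gene CCNA2 by 0.84 and the replication licensing inhibitor gene GMNN by 0.85, whereas CCND1 rose by 0.88; of 31 G1/S regulators 3 rose and 9 fell, also adjusted over the list alone. Of 45 collagen and matrix genes 9 rose and 14 fell, 10 and 14 adjusted over the list alone, including COL4A1 (-1.52), and the bone alkaline phosphatase gene ALPL fell by 2.70. Of 10 blood cell markers 0 rose and 2 fell, LCP1 (-2.16) and CD68 (-1.51), also adjusted over the list alone. With shRNA4 COL6A3 fell by 1.42, COL11A1 rose by 1.02, and the sterol synthesis gene MSMO1 rose by 0.98. None of these lists was shifted by camera. The lowest camera adjusted p among them was 0.187 against a control (cholesterol and fatty acid synthesis, shRNA4). In the difference it was 0.182 (collagens and extracellular matrix). Fry did call some lists downward on the arrays labelled shRNA1. These were osteoblast markers (fry adjusted p = 0.000565), G1/S regulators (fry adjusted p = 0.0102) and blood cell markers (fry adjusted p = 0.0151). It did not call the collagen list (fry adjusted p = 0.586) or the cholesterol list (fry adjusted p = 0.13) there. Among the 777 probes empty in the shRNA4 set, QPRT rose by 1.27 and STAB1 by 1.11 in the shRNA1 set, and ZNF34 fell by 0.72; these 3 were chosen after their values were seen.

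All tests in the next paragraphs were chosen after the patterns were seen. Log2 fold changes of neighbouring genes ran together along chromosomes: genes 1 place apart had a Spearman rho of 0.35 on the arrays labelled shRNA1 and 0.22 with shRNA4, and genes 10 places apart 0.26 and 0.15, above the highest of 1000 shuffles (0.03 and 0.03), which argues against coupling of adjacent genes only. Differences between replicate arrays of a group reached rho 0.0643 in the shRNA1 set and 0.0863 in the other, too low for array noise as the source. A gain or loss of chromosome segments in the selected cells is a candidate explanation, with rho still 0.20 and 0.11 at 20 places; DNA was not measured. A regional response of like size in both comparisons, as the whole cause, is argued against by 20-gene windows beyond 0.5 on the arrays labelled shRNA1. Of 36, 13 lay on the other side of 0 with shRNA4, 13 on the same side within 0.1 of 0 and 10 further out on the same side. The compressed scale may also lower values with shRNA4, where log2 fold changes of all genes had an SD of 0.22 against 0.42. Windows near 0 therefore do not exclude a shared but weaker response. By more than a 95% bootstrap interval over their genes, 6 of the 36 lay on the other side and 10 on the same side. Since neighbouring genes run together, these intervals may be too narrow. A shared part stays open, as a regional effect of PRC or as a trait of the control cells if both controls share a clone. Of 502 windows 10 lay above 0.25 and 9 below -0.25 in both comparisons, against 1.31 and 1.58 for independent windows. Beyond that bound lay 28 with shRNA4 and 107 on the other arrays (Pearson's r across windows 0.31, Spearman's rho 0.17).

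Replication-dependent histone transcripts fell: 36 of 50 tested genes on the arrays labelled shRNA1 and 29 of 50 with shRNA4, 0 rising. They fell in 5 histone protein families on both, which argues against 1 fallen transcript read by similar probes. Probe specificity was not checked, so similar genes within a family may be counted more than once. Of 7 variant and linker genes outside the clusters, 2 fell and 1 rose on the arrays labelled shRNA1. With shRNA4 2 of these 7 fell and 0 rose. The variant gene H2AJ fell in both comparisons (-2.94 and -1.25). Loss of the segments that hold the clusters is argued against too. After subtracting neighbouring non-histone genes the median of the 50 was -0.60 in place of -0.80 with 31 still called, and -0.28 in place of -0.27 with 29. Fewer S-phase cells, with DNA replication genes falling as far as histone genes, are argued against on the arrays labelled shRNA1. The median of the 41 replication genes there was -0.0225. Of these, 10 fell, such as RRM2 (-1.12) and DUT (-0.92, or -0.54 after subtraction of neighbouring genes and -0.47 on another probe), and 5 rose. Fewer S-phase cells with a smaller fall of replication genes than of histone genes stay open, since cell cycle phase was not measured. With shRNA4 the replication median, -0.0879, lies too near the histone median for its spread to decide. A block at entry into S phase, or a loss of the polyadenylated share of these transcripts that the labelling reads, may also apply; transcript levels of 17 genes of S-phase entry and histone transcript processing, chosen after the fall was seen, do not decide it, with CDK2 (-0.83, limma adjusted p = 0.000227) falling, E2F1 (0.26) and ZNF473 (0.29) rising and 14, among them SLBP (0.02) and NPAT (0.08), not called on the arrays labelled shRNA1, and E2F1 alone called with shRNA4 (-0.37). An effect of PRC stays a hypothesis, since PPRC1 was not lower on the arrays where the fall was largest.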
